A study of Homo sapiens with 2 samples.

How the data were processed

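SMC1A ChIP-seq and input DNA of primary human epidermal keratinocytes were analysed, with 1 library each and no replicates; samples were grouped by their titles. Per the labels, chromatin was crosslinked with formaldehyde and precipitated with a rabbit antibody against SMC1. Per the submitters' processing notes, Bowtie, Partek and build hg19 were used; their versions, roles and settings are not given in the sources used here. Peaks were called on the single ChIP library against the single input library.

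The deposited table held 23066 combinations of a peak and a RefSeq transcript, and these peaks lay inside a transcript or up to 5 kb upstream of its start, apart from a small number just past short transcripts; peaks away from genes were not analysed here. The authors gave the reads in RPM for each peak, per the file headers. The authors also gave a p-value per peak, per the file headers, with no adjustment stated. The authors gave a scaled fold change, the ratio of SMC1A ChIP to input, per the file headers; how it was scaled is not given in the sources used here. The p-values of 317 peaks were listed as 0 and the largest was 0.0413. Steps of the RPM values were checked with a tolerance of 0.05 of a step. Implied input reads are estimates: implied ChIP reads times 1.08, divided by fold, where 1.08 is the spacing found among high folds that were not whole numbers, 10 of 34 of which fell on its multiples within 0.004 of a whole number (at most 4 did for any searched spacing over 1% away); their median was 6.18 per peak, so single folds are imprecise. Whole-number folds of 94, 63 and 60 stood beside 74, 46 and 44 implied ChIP reads. If such folds are ChIP counts over 0 input reads, fold and RPM did not count the same reads. Implied input reads are therefore rough.

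Symbols were updated with a RefSeq gene table of GRCh38.p14, used only for names, gene order, length classes and the set of protein-coding genes. No coordinates of it are given. Of 15005 transcripts in the file, 14654 matched by accession, 227 by symbol, 88 by synonym and 36 not at all. There were 15 symbols stored as dates, which were named through their accessions. LOR, an ambiguous older symbol, was resolved by hand to the loricrin gene. Gene lengths of that table were used to sort genes into 10 length classes; in 87.9% of genes the span in the file lay within 20% of it. Peaks on the Y chromosome and at XIST and TSIX were left out. There were 18 peaks on other contigs, kept apart from all comparisons.

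The position of a peak was its midpoint relative to the nearest listed start. The design had foreseen shuffles within chromosomes; because transcripts without peaks are absent from the table used, observed positions were instead set beside uniform placement from 5 kb before the start to the end of each gene's longest listed transcript, with 100 seeded random placements and exact Poisson intervals for ratios. Classes of exons and introns, shuffles across the genome and a scan for the CTCF motif need an hg19 annotation or genome and were not analysed here. Shares have Wilson 95% intervals, differences of shares Newcombe intervals, and the ratio of class medians a bootstrap interval from 1000 resamples of peaks. All intervals cover counting error only.

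A gene counted as having a peak where the file assigned one to it. The 17 gene lists were cohesin and its regulators, epidermal self-renewal, cell cycle and DNA replication, structural genes and enzymes of keratinocyte differentiation, epidermal differentiation transcription factors, hemidesmosome with basement membrane and desmosome, AP-1 and EGFR ligands and receptors, Notch and Wnt signalling, HOX genes, clustered protocadherins, imprinted genes, housekeeping genes, melanocyte markers, dermal fibroblast markers, Langerhans and immune cell markers, liver and neuron genes, and olfactory receptors. Each share was given a percentile among 10000 random lists of protein-coding genes of the same length classes, as a description of this library and not as a test. The gene lists, the windows, the rule for named genes and the first group of other settings named below were fixed before the data were examined. The rule named all cohesin list members, up to 4 members of each other list with the highest fold, up to 2 self-renewal and 2 differentiation genes without a peak in alphabetical order, the 10 highest folds and the 10 genes with the most peaks, ties included. Some genes that this rule names are not reported here.

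The other settings fixed in advance were peaks with a p-value of at most 1e-05, peaks with a fold of at least 4, peaks within 1 kb merged, windows of 1 and 10 kb, any base of the peak in the window, 1 start per protein-coding gene, list genes within 5 kb of a start or without a flank, random lists not matched on length, and RPM in place of fold. Added after seeing the data were the upper 50% of peaks by RPM, the upper quartile by fold, the lists without peaks assigned to 2 or more genes, the differentiation list without the LCE, SPRR and FLG families, and a background without olfactory receptors. The 28 gene families in the closing section were also chosen after seeing the data.

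The placement and list procedures were tested on simulated data. Over 11114 simulated pairs, the ratio within 1 kb of the start was 1.03 with none planted and 5.56 with 30% planted, where 5.65 was simulated. Over 300 simulated lists of 20 genes with no change, drawn from 19392 genes, the mean percentile was 50.7. These lists were drawn at random and genes received peaks independently. The simulation therefore does not cover lists of neighbouring genes or peaks shared between genes. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.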

Results

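The series mapped where SMC1A, a core subunit of the cohesin ring that holds chromatin loops and sister chromatids together, sits in the genome of primary human epidermal keratinocytes. The cells were undifferentiated, grown below confluence without calcium. The data comprised 1 SMC1A ChIP library and 1 input DNA library, with no replicates, so every value below describes this pair of libraries. The authors' fold over input, reads scaled to library size (RPM) and p-value belong to single peaks and carry no replicate error. The peak table covered transcripts and the 5 kb upstream of their starts on build hg19, and peaks away from genes were not analysed here. All RPM values were whole multiples of a single step, which corresponds to 37.9 M reads if 1 step is 1 read, and on that reading the weakest peak held 35 reads and the median peak 51. Intervals are 95% intervals for counting error only.

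The analysed list held 10161 narrow SMC1A peaks in or just upstream of genes on chromosomes 1 to 22 and X. Not all were clearly enriched, since 186 had a fold below 4 and 31 of those a fold below 2. Peaks had a median length of 280 bp, ranging from 150 to 1037 bp, and covered 2869.7 kb in total. Their median fold over input was 9.79, with a 5th percentile of 4.94 and a 95th percentile of 21.9. Of 19392 protein-coding genes in the gene name table, 6443 had a peak (33.2%), and 4326 of those had exactly 1. Any gene absent from the authors' annotation counted as without a peak, here and in the random lists below. How many were absent was not examined. Peaks were also assigned to 598 long non-coding RNA genes and 211 microRNA genes. The share of protein-coding genes with a peak was 13.3% in the shortest of 10 length classes (CI 11.9 to 14.9) and 67.4% in the longest (CI 65.3 to 69.5).

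The peak with the highest fold, 94, lay in SLC43A1, an amino acid transporter gene, at chromosome 11, 57260958 to 57261258. Next came a peak over the starts of PARP2, a DNA repair gene, and RPPH1, the RNA component of RNase P, at chromosome 14, 20811348 to 20811945. That peak had a fold of 86.7 and 26.6 RPM, against a median of 1.35 RPM for all peaks. The rest of the 10 highest folds belonged to PTPRM (63.0), COBL (60.0), EMX2OS (59.0), ITPR1 (58.0), PRKCE (57.2), IRS2 (55.0), LIMK2 (52.9) and CSMD1 (52.0). PTPRM encodes a receptor tyrosine phosphatase, and its peak covered the transcript start. Of the 66 folds of 36 or more, 32 were exactly whole numbers, the pattern that a count of 0 input reads would give. The order among those 32 peaks therefore rests on very few input reads. The peak at PARP2 and RPPH1, with 1008 implied ChIP reads, was not one of them.

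NBPF20 had the most peaks, 36, followed by NBPF9 with 26; both are members of a family of near-identical genes, and the file gave them spans of 2320.9 and 755 kb, 17.1 and 14.7 times their lengths in the gene name table. Their peak counts therefore refer to those spans and not to single gene copies; the same ratio was 14.1 for NBPF8 and lay between 0.84 and 1.001 for the 20 genes outside this family among the 25 with the most peaks. NTM, a neural adhesion gene, and PDE4DIP each had 14 peaks. At least 1 PDE4DIP peak, at chromosome 1, 145058798 to 145059434, was also assigned to NBPF20 and NBPF9, so these counts overlap. NRG1, which encodes a growth factor of the EGF family, and PDE4D, a cyclic AMP phosphodiesterase gene, each had 13. DLGAP1 had 12, ARHGAP26 and BCAR3 had 11 each, and IQCJ-SCHIP1 and NBPF8 had 10 each.

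The next question was where peaks lay within genes. Peaks gathered at transcript starts: 885 covered a start (8.71%, CI 8.18 to 9.27) and another 1273 had their midpoint within 1 kb of one (12.5%, CI 11.9 to 13.2). A further 2029 lay 1 to 5 kb from a start (19.97%, CI 19.2 to 20.8). The remaining 5974 lay more than 5 kb inside a gene (58.8%, CI 57.8 to 59.7). In all, 41.2% of peaks lay within 5 kb of a start (CI 40.3 to 42.2), or 21.2% with a window of 1 kb.

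Start regions held more peaks than uniform placement along the same transcripts would give. Among 11114 pairs of a gene and a peak, 19.1% lay within 1 kb of the start against 6.06% expected, a ratio of 3.15 (CI 3.02 to 3.29), and 100 random placements gave 5.51% to 6.54%. In transcripts of 20 kb or more the ratio was 5.60 (CI 5.28 to 5.94). The first 1 kb upstream of these starts had a ratio of 7.50 (CI 6.97 to 8.05) and the first 1 kb downstream 3.71 (CI 3.35 to 4.11). Between 10 and 20 kb into these transcripts peaks were fewer than uniform placement gives, with a ratio of 0.653 (CI 0.604 to 0.705). Expected numbers add up to the observed total, so an excess at starts lowers the ratio elsewhere. Ratios below 1 in this comparison therefore do not by themselves show depletion. The last 1 kb before the transcript end had a ratio of 1.38 (CI 1.16 to 1.63). Over all 11114 pairs, 40.2% lay within 5 kb of the start against 28.4% expected, a ratio of 1.42 (CI 1.38 to 1.46). At 1 to 5 kb upstream the ratio over all pairs was 1.05 (CI 0.9998 to 1.108), an interval that includes 1. In transcripts of 20 kb or more, however, the 1 kb bins from 5 to 1 kb upstream had ratios of 1.32, 1.37, 1.45 and 1.90. All of these bins had intervals above 1, the lowest bound being 1.10. At 1 to 5 kb downstream the ratio over all pairs was 0.805 (CI 0.752 to 0.861). Over all pairs, the excess within 5 kb therefore lay mainly within 1 kb of the start.

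**Figure D1:**
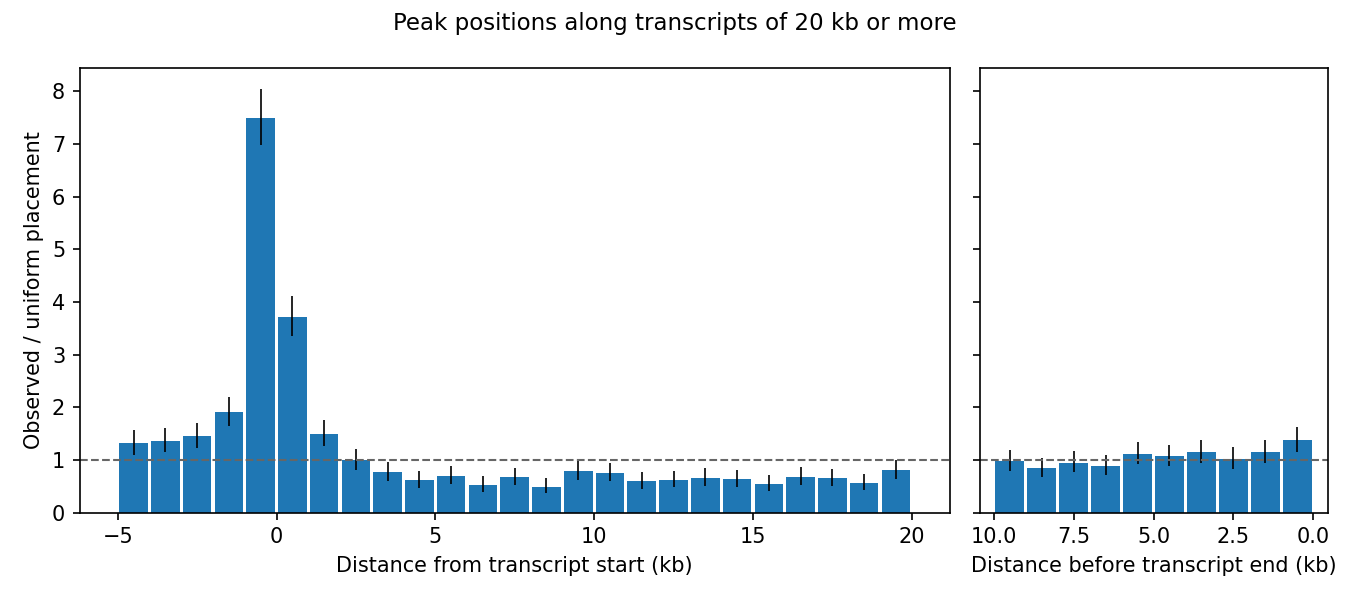
Observed over uniformly expected peak numbers in 1 kb bins, by distance from the transcript start (left, kb, upstream negative) and before the transcript end (right, kb), for transcripts of 20 kb or more in 1 ChIP library. Bars are ratios, lines their 95% Poisson intervals and the dashed line a ratio of 1; the bin just upstream of the start stands at 7.50.

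Enrichment differed little between peak classes. The median fold was 9.29 for peaks covering a start, 9.05 for other peaks within 1 kb, 9.84 for those at 1 to 5 kb and 9.97 for those deeper in genes. The ratio of medians between peaks covering a start and those deeper in genes was 0.932 (bootstrap interval 0.894 to 0.967). By RPM the direction turned: the same classes had medians of 1.40 and 1.32, a ratio of 1.06 (bootstrap interval 1.02 to 1.10).

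Because the cells were undifferentiated, genes of epidermal self-renewal were compared with structural genes and enzymes of keratinocyte differentiation. Of 20 self-renewal genes, 15 had a peak (75%, CI 53.1 to 88.8), against 6 of 29 differentiation genes (20.7%, CI 9.85 to 38.4). Peaks with the highest folds in the self-renewal list belonged to TP63, the master transcription factor of stratified epithelia (25.4), SOX9 (18.99), LRIG1 (18.0) and ITGA6, the basal-cell integrin subunit alpha-6 (14.3). The TP63 peak lay 20710 bp from the start listed in the file, at chromosome 3, 189369926 to 189370130. It was the only peak listed for TP63, whose listed transcripts all shared that start, so no peak lay at another TP63 start. At 1.06 RPM it was below the 25th percentile of all peaks (1.08 RPM), so its fold is imprecise. ITGA6 had 4 peaks, the nearest of them covering a start. BMI1 and DNMT1 were among the 5 members without a peak. In the differentiation list the highest folds were at ALOXE3, a lipoxygenase gene of the skin barrier (17.8), DSC1, a desmosomal cadherin gene (17.4), S100A9 (14.2) and SPRR1B (7.70). ABCA12 and CASP14 were among the 23 members without a peak.

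The difference between these lists was 54.3 percentage points (CI 26.2 to 71.9). Pairs of random lists matched on gene length had a median difference of 14.3 points and a central 95% range from -9.48 to 39.7, and the observed difference stood at percentile 99.87. The self-renewal list itself stood at percentile 99.97 and the differentiation list at 43.9. In the stronger 50% of peaks by RPM, an alternative chosen after seeing the data, the self-renewal share was 30.0%, its percentile 78.9 and the difference 16.2 points, against a percentile of 99.9 for the epidermal differentiation transcription factors in the same peaks. Without the upstream flank the self-renewal share was 50%, at percentile 97.4, and the difference of 36.2 points lay inside its random range of -6.03 to 38.1, at percentile 95.6.

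Among transcription factors of epidermal differentiation, 14 of 18 had a peak (77.8%, CI 54.8 to 91.0; percentile 100). The highest folds there were at CEBPB (18.96), EHF (11.9), KLF4 (11.5) and TFAP2C (11.05). The EHF peak covered the transcript start, and CEBPB had 3 peaks. Adhesion genes of the hemidesmosome, basement membrane and desmosome had a peak in 11 of 15 cases (73.3%, percentile 99.87), with folds of 23.2 at LAMB3, 18.8 at DST and 17.1 at PERP. LAMB3 encodes a chain of laminin-332, and DST, a plakin gene, had 9 peaks. The LAMB3 peak had 0.924 RPM, the minimum of all peaks, so its fold is imprecise.

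Signalling genes were also above random lists. AP-1 and EGFR ligand and receptor genes had a peak in 9 of 14 cases (64.3%, percentile 99.8), with the highest folds at TGFA (13.8), JUN (12.1), ERBB3 (11.1) and EREG (9.32). Without the upstream flank the AP-1 and EGFR share was 35.7%, at percentile 93.0. Notch and Wnt genes had one in 14 of 20 cases (70.0%, percentile 99.89), led by WNT10A (24.4), LGR6 (20.5), WNT4 (19.9) and HEY1 (17.7). Cell cycle and DNA replication genes did not exceed random lists, with 5 of 23 (21.7%, percentile 23.3), among them CDK6 (11.9), MCM3 (11.6), CCND1 (9.57) and CDK4 (8.66). Housekeeping genes stood at 4 of 15 (26.7%, percentile 60.8): TFRC (17.3), YWHAZ (7.52), ACTB (5.97) and GAPDH (4.004).

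**Figure D2:**
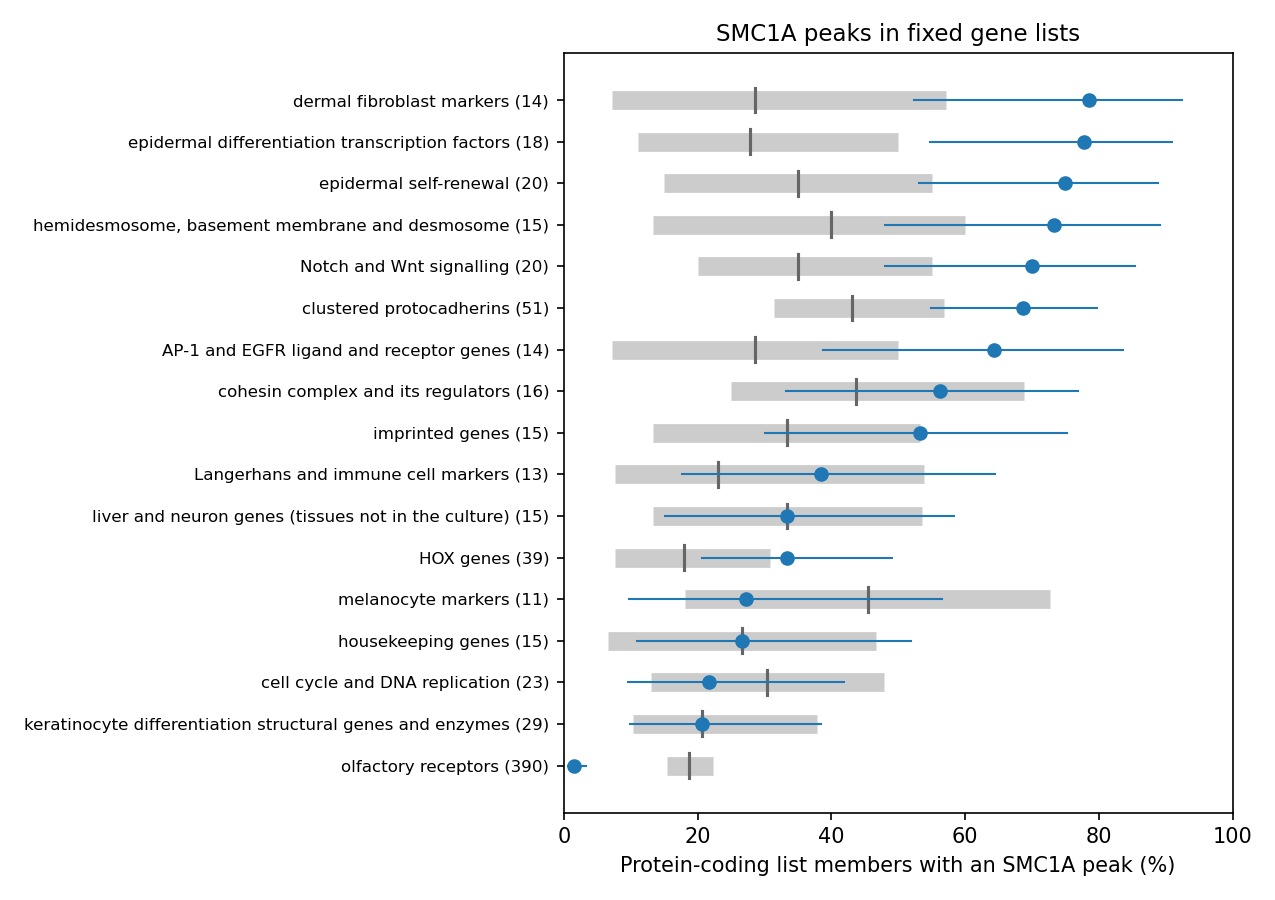
Percent of protein-coding list members with an SMC1A peak in 1 ChIP library, for 17 gene lists with the number of members in parentheses. Points are observed shares with 95% Wilson intervals, grey bars the central 95% of 10000 length-matched random lists and dark ticks their medians; olfactory receptors (1.54%) stand far below their grey bar and dermal fibroblast markers (78.6%) above theirs.

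Genes of other cell types were examined as sets of loci. Dermal fibroblast markers had a peak in 11 of 14 cases (78.6%, percentile 99.98), led by the type I collagen gene COL1A1 (25.7), FAP (17.1), COL1A2 (13.7) and PDGFRB (13.2). The self-renewal share minus the fibroblast share was -3.57 points (CI -29.5 to 26.01), so no difference between these lists was detectable. Melanocyte markers had a peak in 3 of 11 cases (27.3%, percentile 17.2): MLANA (12.3), KIT (7.22) and PMEL (5.65). Langerhans and immune markers had one in 5 of 13 cases (38.5%, percentile 83.4), with the highest folds at SPI1 (18.2), CD14 (14.3), PTPRC (11.5) and CD8A (7.72). Liver and neuron genes had one in 5 of 15 cases (33.3%, percentile 53.5), led by APOA1 (35.8), GAD1 (32.9), RBFOX3 (21.1) and APOB (14.8). Of 390 olfactory receptor genes, 6 had a peak (1.54%, CI 0.707 to 3.32), against a median of 18.7% in random lists. OR2L13 (47.0), OR51B5 (27.7), OR51D1 (14.6) and OR51V1 (12.3) had the highest folds. The OR2L13 fold is a whole number, the pattern that a count of 0 input reads would give, so it is imprecise.

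Gene clusters known for cohesin-dependent regulation were compared with the same background. HOX genes had a peak in 13 of 39 cases (33.3%, percentile 98.7), led by HOXB5 (25.8) and a single peak shared by HOXC4 and HOXC5 (21.9). Without peaks assigned to several genes the HOX share was 10.3%, at percentile 38.3, and without the upstream flank it was also 10.3%, at percentile 50.1. Against random lists not matched on length the HOX list stood at percentile 51.7, and in the stronger 50% of peaks by RPM its share was 15.4%, at percentile 78.9. All 35 protocadherin alpha and gamma genes in the list had a peak and none of its 16 beta genes did, but the listed genes held only 3 distinct peaks. One of them, at chromosome 5, 140306060 to 140306369 with a fold of 10.7, was assigned to PCDHA1, PCDHA2, PCDHA3 and PCDHA4 among others. Counting only peaks within 5 kb of a start, the protocadherin share was 1.96%. Of 15 protein-coding imprinted genes 8 had a peak (53.3%, percentile 96.1), led by DIRAS3 (18.1), GRB10 (13.7), and PEG10 and SGCE, whose shared peak (13.4) covered both starts. The GRB10 peak had 0.924 RPM, the minimum of all peaks, so its fold is imprecise. Without peaks assigned to several genes the imprinted share was 20%, at percentile 27.4, whereas in the stronger 50% of peaks by RPM it was 53.3%, at percentile 99.9.

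Genes of cohesin itself and its regulators had a peak in 9 of 16 cases (56.2%, CI 33.2 to 76.9; percentile 82.2). STAG2 (17.7), STAG1 (13.9) and PDS5A (6.57) had their strongest peak over a transcript start. CTCF, the partner factor that halts cohesin, had a peak 237 bp from its start (14.6), and ESCO1 (9.87) and NIPBL, the cohesin loader (6.02), had one 174 and 667 bp from theirs. SMC3 (9.10), PDS5B (7.41) and MAU2 (4.30) had their strongest peak deeper in the gene. SMC1A itself, RAD21, WAPL, ESCO2, CDCA5, SGO1 and HDAC8 had none. Counting only peaks within 5 kb of a start, 7 of the 16 genes had a peak, at percentile 99.0, whereas in the stronger 50% of peaks by RPM the share was 25%, at percentile 39.0.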

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

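The tests on peak position and on the ribosomal RNA contig, and those on gene length and near-identical genes, were chosen after the result was seen; the test on gene clusters was written before.

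Peaks outside the main chromosomes drew attention because they belong to data that no comparison used. On the unplaced contig gl000220, which carries the ribosomal RNA genes RNA45S5 and RNA5-8S5, 10 peaks had a median fold over input of 1.95, ranging from 1.20 to 5.55. Their median length was 3925.5 bp, against 280 bp elsewhere. Whether repeated copies collected reads in both libraries cannot be told apart from other explanations: implied input reads per kb were 1.39 times those of other peaks, but in 7 of the 8 peaks listed with a p-value of 0 the RPM is too low to be a count over the whole peak, so that ratio decides nothing. How the aligner treated reads with several matches is not given in the sources used here, and no biological explanation was tested.

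The share of self-renewal genes with a peak (75%) was not above that of epidermal differentiation transcription factors (77.8%) or dermal fibroblast markers (78.6%). Self-renewal genes had a peak more often than structural differentiation genes, by 54.3 points. As counted with the upstream flank, gene length did not account for the whole difference, which stood at percentile 99.87 among length-matched pairs of lists. Tandem clusters of list genes alone did not account for the difference either: moving both lists together along the gene order gave a central 95% range from -28.6 to 29.3 points, with the observed value at percentile 99.98. Those moves did not keep gene length, and the length-matched lists did not keep clusters, so length and clusters together were not tested. Without the LCE, SPRR and FLG families, where reads can be shared between near-identical genes, 5 of 18 differentiation genes had a peak and the difference of 47.2 points stood at percentile 99.57. The difference lay inside its length-matched range in the stronger 50% of peaks (16.2 points, percentile 73.6) and without the flank (36.2 points, percentile 95.6), which leaves open that it rests on weaker and upstream peaks, and no biological explanation was tested, since the series holds 1 state of the cells.

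Peaks were concentrated within 1 kb of transcript starts. Higher background in both libraries at open promoters, as the whole cause, would remove the concentration among the peaks most enriched over input. In the upper quartile of fold the ratio over uniform placement was still 2.98 (CI 2.71 to 3.27). A partial share of background is left open. That ratio is below the interval for all peaks (3.02 to 3.29), and peaks covering a start had a lower median fold than deeper peaks (9.29 against 9.97). A minority of short transcripts did not account for it, since transcripts of 100 kb or more had a ratio of 9.55 (CI 8.62 to 10.5). Capture of open chromatin in the ChIP library alone, which an input library does not show, stays open, and no biological explanation was tested.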

How the results depend on the processing

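The alternatives with the upper 50% of peaks by RPM, the upper quartile by fold, without peaks of 2 or more genes and without the LCE, SPRR and FLG families were chosen after seeing the data. Limits of p-value and fold left 10100 and 9975 of 10161 peaks. They removed so few peaks that little could change. Location shares, placement ratios and list differences stayed within their intervals. The CTCF motif alternatives and the flank of 50 kb around genes were not run, because the genome and the peaks away from genes were not used here; the window of 10 kb extends downstream of starts only. With the upper 50% by RPM, 5143 peaks were left, by construction; 42.2% lay within 5 kb of a start, 9.62% covered a start, 10.6% lay within 1 kb, 22.01% at 1 to 5 kb and 57.8% deeper, and the placement ratio was 2.86. There the self-renewal share was 30.0% and its difference from differentiation genes 16.2 points; the cause was not tested. The placement ratio was 2.98 in the upper quartile of fold. The share within the window was 21.2% at 1 kb and 47.5% at 10 kb, by construction, and 37.1% with 1 start per protein-coding gene. Without a flank the self-renewal share was 50% and its percentile 97.4, the AP-1 and EGFR share 35.7% at percentile 93.0 and the HOX share 10.3% at percentile 50.1; shares fall there by construction. The difference between self-renewal and differentiation genes was 36.2 points there, at percentile 95.6 among length-matched pairs, and 39.3 points without peaks of 2 or more genes, at percentile 98.2. With RPM in place of fold the ratio of class medians reversed to 1.06; the cause was not tested. The protocadherin percentile reversed to 0.005 within 5 kb of a start and to 0 without peaks of 2 or more genes, since 3 shared peaks carry that list. Of 17 list percentiles, 16 stayed on their side of the central 95% range without length matching, 15 within 5 kb of a start, 14 without a flank and 14 with the upper 50% by RPM. HOX genes lost their place above that range without length matching (51.7), with the upper 50% by RPM (78.9) and without peaks of 2 or more genes (38.3), the last of which also took imprinted genes to 20%, at percentile 27.4. With the upper 50% by RPM imprinted genes stood at percentile 99.9 and the cohesin list at 39.0. Depth limits single folds, since the median peak had about 6.18 implied input reads. That number is rough. It rests on the spacing of the high folds and on fold and RPM counting the same reads, which the whole-number folds go against.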

Other observations

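All gene families and genes in this part were chosen after their values or those of other lists were seen. Among 28 gene families grouped by symbol, collagen genes exceeded their length-matched range, with a peak in 31 of 44 genes (70.5%, against a random median of 52.3%). Zinc finger genes named ZNF, most of them encoding DNA-binding repressors, fell below theirs, with 76 of 516 (14.7%, against 31.2%). Keratin-associated protein genes of the hair shaft had a peak in 3 of 94 cases (3.19%, against 12.8%), and none of 39 beta-defensin genes had one. Keratin genes (13 of 55), ribosomal protein genes (25 of 95) and core histone genes (10 of 64) lay inside their ranges, as did 24 of the 28 families in all. With 28 families tried, 1 family above a central 95% range can arise by chance. COL1A1 and COL1A2, among other collagen genes, had also been counted in the lists above. Random lists drew genes independently, and reads shared between similar genes of a family were not examined here.

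SENP5 held the peak with the most reads, 102 RPM, but its fold was 1.14. LINC00486 had 35.3 RPM with a fold of 2.09, and SH3RF3 had 4.94 RPM with a fold of 1.43. DHX8 had 9.27 RPM with a fold of 33.2 over its start, and SCNN1G, a subunit gene of the epithelial sodium channel, 7.58 RPM with a fold of 48.6.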
